A study of Homo sapiens with 22 samples.

How the data were processed

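Cells were grown in RPMI with 10% FBS and RNA was taken at 80% confluence, per the labels' protocols. Stranded libraries of polyadenylated RNA were made with dUTP marking of the second strand and 15 PCR cycles, per the labels' protocols. The submitters' processing notes name Bowtie2, RSEM and hg19, and their versions and settings, including the strand setting, are not given in the sources used here. The deposited expected count of each gene is the authors' RSEM estimate of its reads, which is fractional where reads are shared, per the file headers. The deposited TPM values of each gene was computed by the authors with RSEM from these counts and effective gene lengths, per the file headers. Each of the 22 files lists 25343 gene symbols. Between 27.2% and 31.2% of the values of a library were not whole numbers.

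Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr at a minimum count of 10, robust quasi-likelihood fits and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. There were 3 fits: the 16 CRISPRi libraries, the 6 libraries of the lines, and SC with M1A. M1A is short for the line whose label is that of 786-O with M1A in place of the O. Comparisons were iMAE-1.1, iMAE-1.2 and iMAE-126 versus SC, iMAE-1.2 versus iMAE-1.1, iMAE-126 versus the mean of iMAE-1.1 and iMAE-1.2, M1A versus 786-O, OS-LM1 versus M1A, and SC versus M1A. Levels are CPM, counts per 1e6 of the library total multiplied by its TMM factor, with the factors computed over all 22 libraries.

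For each comparison the 6 called genes with the largest rise and fall were named if a group had a mean of at least 5 CPM and no library of the groups overlapped. Another 12 genes were always named, with up to 6 genes per direction called in both iMAE-1.1 and iMAE-1.2 and up to 4 called genes of each list that camera called or that had at least 3 called members. The 28 gene lists were written from general knowledge and tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and, as an alternative, an estimated one. The adjusted p of camera is over the lists of a comparison. The version with an estimated correlation also tests with the residual degrees of freedom of the fit (libraries less fitted terms). These are few in the fits of the lines and of SC with M1A, which leaves it little power there. Genes called between M1A and 786-O with a log2 fold change of at least 1 were tested as 2 sets in the CRISPRi comparisons. For groups with at most 3 counts, folds are ratios with exact 95% intervals, and for groups with 0 counts they are lower bounds at a floor of 3 counts over the group.

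The comparisons, gene lists, tests and most alternatives were chosen before the data were examined. Those alternatives were DESeq2 1.42.0, RLE factors, no filter, a minimum count of 50, limma on log2(TPM + 1), the replicate number as a block, the compared groups alone, subsets of SC, a threshold of 1 on the log2 fold change, and each library left out in turn. Library set as a term, SC replicates 3 to 6 as controls, SC subsets against M1A, controls that are not shared, and crossed replicate numbers were added after seeing the data. The library set was inferred from the mean length of the genes that reads came from. An alternative whose sign differed while neither value passed the threshold is not counted as reversed.

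Labels were exchanged between groups in all 35 splits of 4 and 4 libraries, or in 100 drawn of the 210 splits of 4 and 6, and tested in the same way. Similarity of responses was compared with simulated groups without change. The method was tested on simulated data with 200 changed genes per comparison. Of the genes changed 1.5-fold (67 genes), 2-fold (67) and 4-fold (66), it recovered 32.8%, 68.7% and 93.9% in iMAE-1.1, 58.2%, 79.1% and 93.9% in iMAE-1.2, and 25.4%, 67.2% and 89.4% in iMAE-126. It recovered 34.3%, 71.6% and 90.9% in iMAE-1.2 versus iMAE-1.1, and 22.4%, 68.7% and 87.9% in M1A versus 786-O. In OS-LM1 these were 35.8%, 76.1% and 84.8%, and in SC versus M1A 5.97%, 43.3% and 81.8%. False calls numbered from 2 of 89 to 11 of 165. The simulated libraries varied independently and had no library sets, so these rates may not describe the real comparisons. No file repeated another, and replicates differed by more than counting noise, with a mean chi-square per gene of 2.24 to 87.0. The values of 61.1 to 87.0 were all between SC replicates 1 or 2 and SC replicates 3 to 6. Among SC replicates 3 to 6, the pairs 4 with 6 (2.24) and 3 with 5 (3.03) were closer than the others (5.79 to 8.94). These libraries may therefore not be independent. Genes of the sex chromosomes that mark donor sex were not analysed here, nor were single transcripts. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.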

Results

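Polyadenylated RNA of human renal cancer cell lines was sequenced in 22 libraries that fall into 7 groups. The line 786-O, from a clear cell renal carcinoma, gave 2 libraries. Its metastatic derivative gave 2 and is called M1A here. In the sample and figure labels its name is that of its parent with M1A in place of the O. OS-LM1, a metastatic renal cancer line of another origin, gave 2. The labels call each a renal cancer cell line, and their relations are known from earlier work. The other 16 libraries came from M1A cells under CRISPR interference (CRISPRi), in which a Cas9 that does not cut DNA carries a repressor to the site that a guide RNA names. Of these, 6 had a non-targeting guide (SC), 4 the guide iMAE-1.1, 4 the guide iMAE-1.2 and 2 the guide iMAE-126. The study profiles enhancers in metastatic cancer, and MAE stands for a metastasis-associated enhancer. The labels do not say which element or gene each iMAE guide targets.

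The total of expected counts per library, in units of 1e6, ranged from 9.06 (iMAE-1.2 replicate 1) to 52.7 (M1A replicate 1). It was 52.7 and 49.3 in M1A, 39.7 and 41.8 in 786-O, and 25.8 and 15.6 in OS-LM1. It lay between 10.5 and 24.4 in SC, 11.8 and 22.1 in iMAE-1.1, 9.06 and 23.7 in iMAE-1.2, and 19.9 and 36.2 in iMAE-126. Between 16877 and 18514 of the 25343 listed genes had a count in a library. Whether the replicates of a group were separate cultures is not stated in the sources used here, so the p-values measure the spread between libraries, which may be technical in part. Counting intervals and floors cover counting error only.

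The CRISPRi libraries fell into 2 sets that the labels do not name. The mean length of the genes that reads came from was 3528 to 3716 bases in SC replicates 1 and 2 and both iMAE-126 libraries (set A), and 3264 to 3395 bases in the other 12 CRISPRi libraries (set B). In M1A it was 3929 and 3982 bases. The first principal component of the CRISPRi libraries separated set A from set B and held 67.6% of the variance of 6290 genes. The second component held 13.2%. All iMAE-1.1 and iMAE-1.2 libraries lie in set B and both iMAE-126 libraries in set A, while SC lies in both. The split was found after the data were seen, so tests without it are given as planned, and values with library set as a term of the fit stand beside them where they matter.

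**Figure D1:**
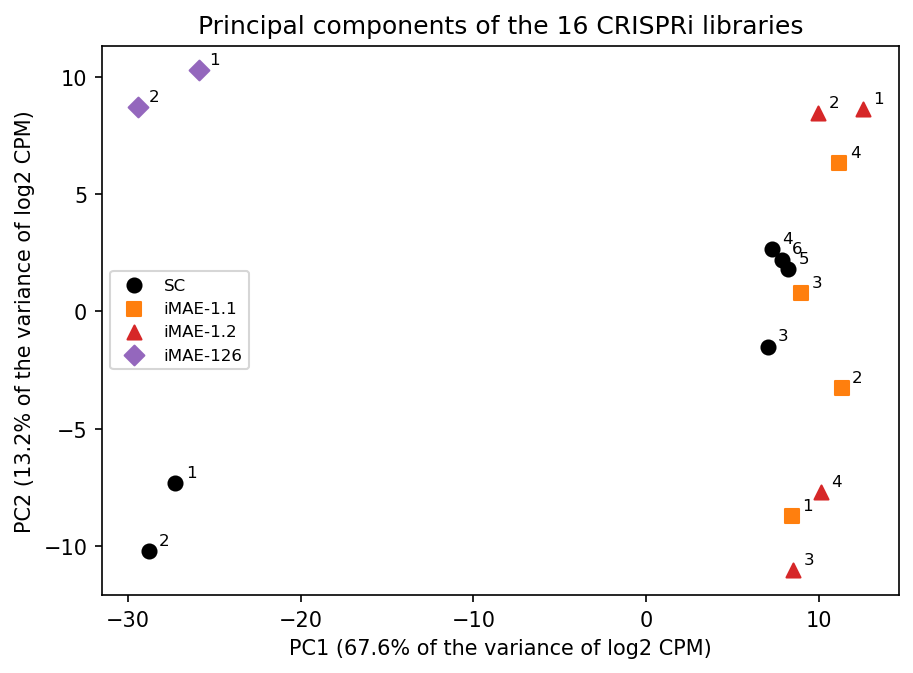
Scores of the 16 CRISPRi libraries on the first and second principal components of log2 CPM, which hold 67.6% and 13.2% of the variance. Each point is a library with its replicate number, and SC replicates 1 and 2 lie with both iMAE-126 libraries on the left.

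CXCR4 encodes the receptor of the chemokine CXCL12, and CYTIP encodes an adaptor of lymphoid cells that limits cell adhesion. Earlier work on these lines tied both genes to metastasis, so naming them here is not independent evidence. CXCR4 had 240 counts in M1A and 3 in 786-O, a ratio of 69.7 with a 95% counting interval of 23.6 to 341 (edgeR adjusted p = 0.000118). Its level was 2.79 and 2.42 CPM in the M1A libraries and 0.026 and 0.048 CPM in those of 786-O. CYTIP was at 65.5 and 62.6 CPM in M1A and 0.283 and 0.266 CPM in 786-O, a log2 fold change of 7.85 (adjusted p = 3.12e-07). In SC, CXCR4 lay between 0.587 and 1.54 CPM in 6 of 6 libraries, below M1A, with a log2 fold change of −1.41 (adjusted p = 0.00830). That call was lost without M1A replicate 1 (adjusted p = 0.0709) or replicate 2 (adjusted p = 0.0567).

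CXCR4 was lower in each of the 10 libraries with an iMAE guide, at 0 to 0.319 CPM, than in any SC library. It fell by 3.86 on the log2 scale in iMAE-1.2 (adjusted p = 0.0218) and by 3.46 in iMAE-126 (adjusted p = 0.00784). In iMAE-1.1 the log2 fold change of −2.62 did not pass the test (adjusted p = 0.0634). The summed counts were 100 in SC, 10 in iMAE-1.1, 4 in iMAE-1.2 and 5 in iMAE-126, so each of these values rests on few reads. The call in iMAE-1.2 was lost without iMAE-1.2 replicate 1 (adjusted p = 0.0759), replicate 3 (0.0659) or replicate 4 (0.0835). The call in iMAE-126 was lost without its replicate 1 (adjusted p = 0.0966) or replicate 2 (0.0536), where the lone library is assumed to vary like the other groups. With library set as a term the changes were −2.31 in iMAE-1.1 (adjusted p = 0.0550), −3.55 in iMAE-1.2 (0.00957) and −3.88 in iMAE-126 (0.00297). Of 12 measured genes of the list of CXCR4 and its neighbours on chromosome 2, 0 were called in iMAE-1.1, 1 fell in iMAE-1.2 (CXCR4) and 2 fell in iMAE-126, and camera did not call the list (adjusted p = 0.197, 0.319 and 0.523). CXCR4 did not differ between iMAE-1.2 and iMAE-1.1 by the test (log2 fold change −1.25, adjusted p = 1.00).

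CYTIP did not pass the test in any CRISPRi group against all SC libraries, with log2 fold changes of 1.26 in iMAE-1.1 (adjusted p = 0.253), 1.38 in iMAE-1.2 (0.192) and 0.71 in iMAE-126 (0.499). Its level in SC depended on the library set, at 8.60 and 10.0 CPM in set A and at most 1.86 CPM in set B. With library set as a term CYTIP rose by 2.63 in iMAE-1.1 (adjusted p = 0.0116) and by 2.73 in iMAE-1.2 (0.00860). In iMAE-126 the term gave −0.39 (adjusted p = 0.666).

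**Figure D2:**
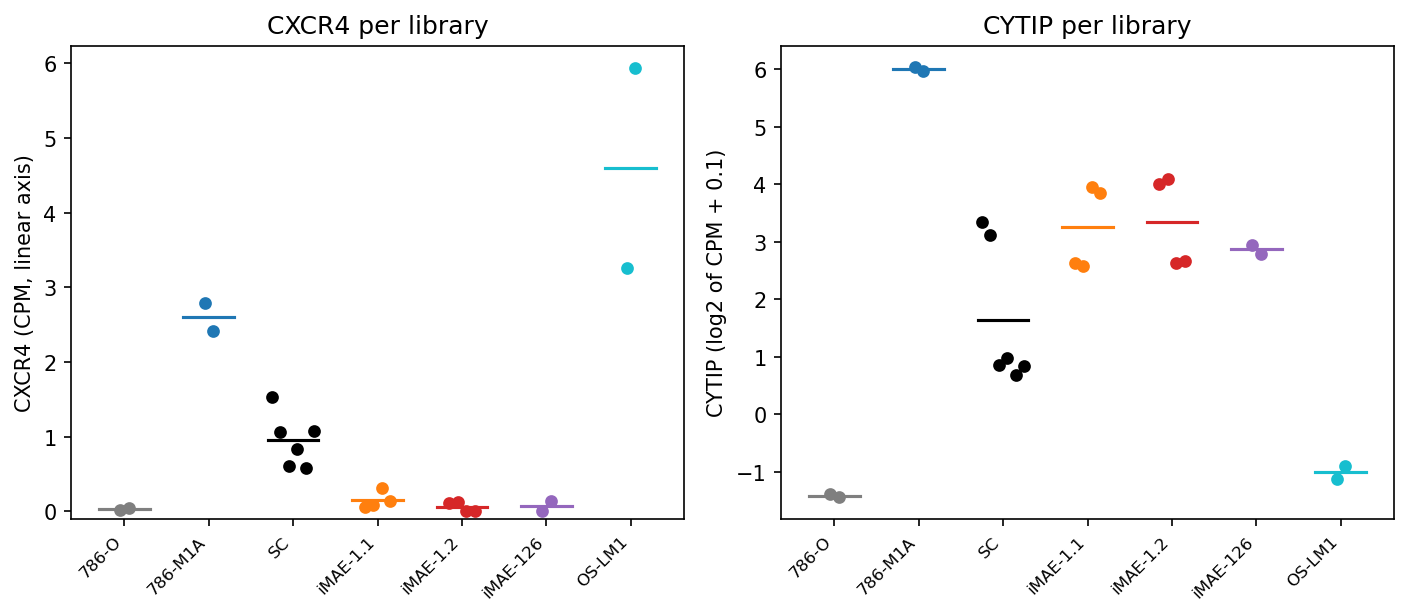
CXCR4 in CPM on a linear axis and CYTIP as log2 of CPM + 0.1, with a point per library and a bar at the mean of each of the 7 groups. CXCR4 lay at 0.587 to 1.54 CPM in SC and at 0 to 0.319 CPM in the 10 libraries with an iMAE guide.

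To find what sets the metastatic derivative apart from its parent, M1A was compared with 786-O. Genes that rose with CYTIP included PDGFRB, a receptor for platelet-derived growth factor (log2 fold change 5.95). GFRA2, a receptor for neurturin (5.15), the growth factor carrier IGFBP1 (4.82) and the collagen COL6A3 (4.76) rose as well. The tyrosine phosphatase gene PTPRS had 0 counts in M1A against 2172 in 786-O, at least 830-fold lower at a floor of 3 counts over the group. The WNT carrier gene WLS (−9.02) and the basement membrane collagen COL4A5 (−8.25) fell too. TEX15, a germ cell gene, was 603 times lower (95% counting interval 167 to 4988), and LRCH2 was 339.5 times lower (116 to 1649). ENPP4, an ectoenzyme gene, was 639 times lower (114 to 25279).

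Of 26 measured members of the hypoxia and HIF list, 16 rose and 1 fell in M1A, with a median log2 fold change of 0.62. They included LOX, which crosslinks collagen (3.66), the hormone STC2 (1.72), the hypoxia sensor EGLN3 (1.49) and the angiogenic factor VEGFA (1.42), and the list also holds CXCR4 and CYTIP. EPAS1, the HIF subunit active in these VHL-deficient cells, rose by 0.62 (adjusted p = 0.0181), and HIF1A fell by 0.96 (adjusted p = 0.000564). The EPAS1 call was lost without any 1 of the 4 libraries: M1A replicate 1 (adjusted p = 0.107) or 2 (0.0978), or 786-O replicate 1 (0.121) or 2 (0.133). VHL itself did not pass the test (−0.27, adjusted p = 0.0818), nor did PAX8, a renal lineage regulator (0.02, adjusted p = 0.919). Of 26 NF-kB targets, 12 rose and 4 fell, the rises including the chemokines CXCL1 (2.50) and CXCL8 (2.47) and the cytokine IL6 (2.29). Of 18 matrix proteases and plasminogen genes, 11 rose, among them the gelatinase MMP2 (4.33) and the urokinase receptor PLAUR (1.55). Another 3 fell, with the matrilysin MMP7 (−6.39) and the collagenase MMP13 (−2.95) among them. VIM, an intermediate filament of mesenchymal cells, rose by 0.82 (adjusted p = 0.000358), and CDH1, the epithelial cadherin, did not pass the test (−0.68, adjusted p = 0.0696).

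Transcripts of 20 of 21 sterol and SREBP genes fell in the metastatic line, with a median of −0.89 (camera adjusted p = 0.477 with an estimated correlation), among them the desaturase SCD (−3.17), HMGCS1 (−1.60) and DHCR7 (−1.55) of the cholesterol pathway. Of 31 interferon response genes, 18 fell and 2 rose, with IFI27 at −3.28 and the antiviral RSAD2 at −2.62. The list of renal lineage and tubule genes, called tubule genes in the text, was mixed. It had 11 of 21 lower, such as the sodium pump subunit FXYD2 (−4.67), CDH16 (−3.14) and PAX2 (−2.61). Another 4 were higher, such as the neprilysin gene MME (2.72). Of 5 class II histocompatibility genes 4 fell, HLA-DPA1 by a ratio of 136 (95% counting interval 24.0 to 5436). Immediate-early genes had 13 of 24 members higher, such as KLF4 (1.62) and ETV5 (1.63), and 2 lower, EGR1 among them (−1.38). Among replication and mitosis genes 7 of 30 rose, such as the origin licensing gene CDT1 (0.66), a call lost without 786-O replicate 2 (adjusted p = 0.0543), and none fell.

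The edgeR test called 5065 of 16354 genes, 2398 higher and 2667 lower in M1A, of which 1931 changed by at least 1 on the log2 scale. The camera test with a preset correlation called the hypoxia (adjusted p = 2.46e-06), NF-kB (0.00307), protease (0.0202), sterol (9.12e-08), interferon (0.000128), class II (0.0114), immediate-early (0.00148) and proliferation lists (0.0202). It also called YAP and TAZ targets (0.0221), with 5 of 18 higher and 2 lower, and heat shock genes (0.0216), with 4 of 12 higher and 1 lower. None of these 10 lists was called with an estimated correlation, where the adjusted p ranged from 0.461 to 0.607. That version has few residual degrees of freedom in the fit of the lines, so its outcome does not decide whether these calls hold. The tubule list was not called with the preset correlation (adjusted p = 0.0726). Adjusted over the list alone, 17 hypoxia genes were higher, 12 NF-kB targets higher, 12 protease genes higher, 20 sterol genes lower and 19 interferon genes lower. A fit of these 4 libraries alone called 8733 genes. The main fit also takes its spread from the OS-LM1 libraries. Their mean chi-square per gene was 30.2, against 7.43 in M1A and 5.51 in 786-O. Without 786-O replicate 2 the test called 2259 genes, and 27 of 111 calls of named genes were lost. It called 2405 without 786-O replicate 1, 2475 without M1A replicate 1 and 2551 without M1A replicate 2, where the lone library is assumed to vary like the other lines.

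To see what the vector with a non-targeting guide does to the parent cells, SC was compared with M1A. CYTIP (−3.86), the matrix protein MXRA5 (−3.93) and PGF, a ligand of the VEGF receptor (−3.65), fell, as did IGFBP4 (−3.52), CCDC152 (−3.50) and the aminopeptidase ANPEP (−3.44). The matrilysin MMP7 rose by 4.33, and so did SATB1, an organiser of chromatin loops (5.27), and LDLRAD2 (6.11). The tendon factor SCXB rose by 4.28, a value that is uncertain because it has a near-identical copy, and SAPCD1 had 0 counts in M1A and 885 in SC, at least 273-fold higher, which is uncertain because it overlaps a neighbouring gene. Of 23 hypoxia genes 16 fell and none rose, with a median of −1.04, including LOX (−2.49) and the collagen hydroxylase P4HA1 (−1.30). EPAS1 fell by 1.58 (adjusted p = 0.0121), while HIF1A did not pass the test (0.10, adjusted p = 0.563). PAX8 rose by 1.04 (adjusted p = 0.0116). Both calls were lost without M1A replicate 1 (adjusted p = 0.0667 for EPAS1 and 0.0692 for PAX8) or M1A replicate 2 (0.0761 and 0.0998). Without M1A replicate 2 those of CCDC152 and SCXB were lost too (both 0.0539).

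Sterol genes went up in SC, 14 of 21 with none lower (median 0.58), as SCD (1.75) and DHCR7 (1.37) show. Of 31 interferon genes 19 rose and 3 fell, with the antiviral synthetases OAS2 (2.43) and OAS1 (1.97) among the rises. Of 33 ribosomal protein genes 23 rose and none fell, by a median of 0.44. Proliferation genes were lower, 20 of 30, such as the ribonucleotide reductase subunits RRM1 (−1.06) and RRM2 (−0.94), and 2 were higher. Of 17 YAP and TAZ targets 9 fell, such as the tissue factor gene F3 (−1.99) and NT5E (−1.73). Glycolysis genes fell in 8 of 18, such as the hexokinase HK1 (−1.21, not called without M1A replicate 2, adjusted p = 0.0514), and the unfolded protein response in 7 of 16, such as EDEM1 (−1.05).

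The test called 7832 of 14769 genes, 4100 higher and 3732 lower in SC. On TPM with limma the split was 2516 higher and 5032 lower, and the median of all genes differed by −0.27. Test and scale changed together, so the cause was not tested. The medians of the lists named here kept their sign. The camera test called these 8 lists with the preset correlation, at adjusted p of 0.000165 (hypoxia), 0.000295 (sterol), 0.00161 (interferon), 0.000246 (ribosomal and proliferation), 0.00954 (YAP and TAZ) and 0.0354 (glycolysis and unfolded protein response). With an estimated correlation the adjusted p ranged from 0.515 to 0.731. That version has few residual degrees of freedom in this fit, so its outcome does not decide whether the calls hold. Adjusted over the list alone, 16 hypoxia genes were lower, and 15 sterol, 20 interferon and 24 ribosomal genes were higher. The calls numbered 3035 without M1A replicate 1 and 2002 without M1A replicate 2, which also lost 37 of 108 calls of named genes. SC and M1A share no library set, so a difference in library preparation cannot be told apart from the vector. The fit also pools SC libraries of both sets, so each change is a mean over sets that differ for genes such as CYTIP. With SC replicates 1 and 2 alone 7708 genes were called, and with SC replicates 3 to 6 alone 11544.

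To find what the iMAE-1.1 and iMAE-1.2 guides do, each was compared with SC. The aromatic hydrocarbon and estrogen hydroxylase CYP1B1 fell by 1.66 in iMAE-1.1 and by 1.78 in iMAE-1.2, and the metallothionein MT1L fell too (−4.52 and −4.36). MT1L belongs to a family of near-identical genes, so its counts are uncertain. The guanylate cyclase subunit GUCY1A3 (−1.14 and −1.35), the interleukin-1 receptor IL1R1 (−0.89 and −1.03) and the p53-induced TP53INP1 (−0.99 and −0.95) fell under each guide. The methyltransferase NNMT (−0.52 and −0.57) and MTSS1, a regulator of actin at membranes (−0.62 and −0.54), fell less. F3, which starts blood coagulation, rose by 1.31 and 1.35 and lay at 206 to 277 CPM in all 8 libraries against 74.3 to 136 CPM in SC. PDGFRB (1.25 and 1.34), the dynein adaptor CCDC64 (1.47 and 1.51), SPOCD1 (1.03 and 1.04) and the antisense RNA VPS9D1-AS1 (1.06 and 1.08) rose with it. VPS9D1-AS1 is uncertain, since the strand setting of the counting is not given in the sources used here.

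The median of 31 interferon genes was −0.46 in iMAE-1.1 and −0.53 in iMAE-1.2, with few genes called, and the list was not called with an estimated correlation (camera adjusted p = 0.115 and 0.0884). Without library set as a term, 2 of them fell in iMAE-1.1, IFIT3 (−0.51) and OAS3 (−0.36). In iMAE-1.2 4 fell, including IFIT1 (−0.89). The peptide transporter TAP1 of antigen presentation fell by 0.55 and 0.56. No sterol gene of 21 passed the test over all genes in the fit without library set as a term. Adjusted over the list alone, 8 were lower in iMAE-1.1 and 10 in iMAE-1.2, with medians of −0.22 and −0.26. For interferon genes those numbers were 18 and 17. The hypoxia genes ADM, a vasodilator peptide (0.60 and 0.58), and ENO2, an enolase (0.50 and 0.51), rose under each guide. In iMAE-1.2 the collagens COL1A1 (−0.77) and COL4A2 (−0.59) and the membrane protease MMP14 (−0.50) fell. MME fell in iMAE-1.1 (−0.76), and SIM1, a renal lineage factor, fell in iMAE-1.2 (−1.43).

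The test called 69 of 15254 genes in iMAE-1.1, 29 higher and 40 lower, and 110 in iMAE-1.2, 54 higher and 56 lower. All 29 higher genes of iMAE-1.1 and 27 of its 40 lower ones were called the same way in iMAE-1.2. Both comparisons use the same SC libraries, which by itself favours shared calls, and so would an exchange of labels between the guides, which is not excluded. DESeq2 called 424 genes in iMAE-1.1. In iMAE-1.2 the split was 248 higher and 411 lower with DESeq2, and 24 higher and 81 lower on TPM with limma, where the median of all genes differed by −0.10. The term of library set gave other counts: 273 genes were called in iMAE-1.1 and 417 in iMAE-1.2, including 68 and 107 of those called without it, and 117 higher and 106 lower genes were shared. Against SC replicates 3 to 6, the controls of set B, 236 and 383 genes were called. The camera test with the preset correlation called the interferon list (adjusted p = 3.27e-11 in iMAE-1.1 and 2.28e-11 in iMAE-1.2), the sterol list (5.78e-06 and 3.68e-07) and the class I antigen presentation list (1.74e-05 and 0.000261). With an estimated correlation these were not called, at 0.0884 to 0.131. The lymphoid list was called upward (0.000548 and 0.000443), and the mesenchymal (0.00202 and 0.000755), protease (0.00775 and 0.0216), tubule (0.0065 and 0.0217) and unfolded protein lists (0.00119 and 0.0186) downward, again not with an estimated correlation (0.0884 to 0.491). With library set as a term the tubule list was not called (0.0788 and 0.225), and its median went from −0.41 to −0.05 in iMAE-1.1 and from −0.33 to −0.04 in iMAE-1.2. The unfolded protein median went from −0.18 to −0.07 and from −0.13 to −0.06, and the mesenchymal median from −0.32 to −0.13 and from −0.26 to −0.17. In iMAE-1.1 the immediate-early (0.00282) and NF-kB lists (0.0307) were called upward (0.131 and 0.809 with an estimated correlation), and the NF-kB median turned from 0.27 to −0.04 with library set as a term (adjusted p = 0.739). With both the term and an estimated correlation the interferon list was not called (0.0977 and 0.113), nor was the class I list in iMAE-1.2 (0.0916). The sterol list was called, at 0.00123 and 0.000915. The lymphoid list (0.0289 and 0.0187), the protease list (0.0289 and 0.0444) and, in iMAE-1.1, the class I list (0.0383) were called too. So was the hypoxia list, at 0.0289 and 0.0187, where 6 of 23 genes rose in iMAE-1.1 and 9 in iMAE-1.2, although its median of 0.06 and 0.04 without the term turned sign on TPM.

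These counts fell when any single library of the compared guide was left out. Without iMAE-1.1 replicate 2 the test called 16 genes in iMAE-1.1, and 14 of 23 calls of named genes were lost. It called 20 without replicate 1, 33 without replicate 3 and 18 without replicate 4. Without iMAE-1.2 replicate 4 it called 11 genes in iMAE-1.2, and 20 of 31 calls of named genes were lost. It called 17 without replicate 1, 33 without replicate 2 and 24 without replicate 3. Leaving out SC replicates 1, 2, 3, 4 or 6 gave 52, 50, 59, 43 or 59 genes in iMAE-1.2. The calls of F3, CCDC64, VPS9D1-AS1, CYP1B1, MT1L, C3orf14 and NNMT held in both groups without any single library.

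Across 15254 genes the log2 fold changes of iMAE-1.1 and iMAE-1.2 had a Pearson correlation of 0.815. Unchanged groups simulated against the same controls gave 0.125. The covariance was 0.0966 against 0.00520 in the simulation, a difference of 0.0914. With SC divided so that the guides shared no control, the correlation averaged 0.450, and it averaged 0.410 with pairs of SC replicates 3 to 6, where the covariance was 0.0472. The simulation did not include the library sets, which both comparisons with all SC libraries share. If labels of 2 libraries of each guide were exchanged, each group would mix both guides, and this alone would give a high correlation, shared calls and no differing genes. Genes are not independent replicates. Compared with each other, iMAE-1.2 and iMAE-1.1 differed in 0 genes by edgeR, with 116 at an unadjusted p under 0.05. DESeq2 called 2 genes, limma on TPM called 0, and edgeR called 0 with library set as a term, with 218 at an unadjusted p under 0.05. In simulated data this comparison recovered 71.6% of 67 genes changed 2-fold. The 8 libraries also fell into 2 blocks that cross the guides, with 1385 genes called between the blocks. The fit does not model this structure within each guide, so 0 calls do not show that the guides act alike, and the recovery may be lower than simulated.

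To find what the iMAE-126 guide does, its 2 libraries were compared with SC. MMP7 rose by 3.05, from 5.58 to 8.28 CPM in the 6 SC libraries to 53.8 and 59.8 CPM, and the complement regulator CFI rose by 2.83. The exchange factor VAV3 (2.89), ELFN1 (2.81), the hyaluronan-binding protease HABP2 (2.72) and C2CD4C (2.67) rose as well, although SC libraries of set A already lay above those of set B, for HABP2 at 9.62 and 8.47 CPM against 0.614 to 1.01. The rises were 3.02 for MMP7, 1.95 for CFI, 1.56 for VAV3, 1.62 for ELFN1 and 1.43 for HABP2 with library set as a term, and C2CD4C was not called (adjusted p = 0.0914). Of 24 NF-kB targets 17 fell, by a median of −1.21 over the list, including CXCL8 (−3.75), CXCL1 (−2.47), the laminin subunit LAMB3 (−1.39) and the adhesion receptor ICAM1 (−0.96). IL6 (−3.26) and CCL2 (−3.03) of that list fell as well, and so did TNF (−3.35) and the growth factor CSF2 (−3.74). Under the term of library set the list median was −0.44, with 9 lower and 1 higher, and the changes were −1.88 for CXCL8, −1.24 for TNF, −0.96 for IL6 and −2.68 for CSF2, and CCL2 was not called (adjusted p = 0.0944). HYPK (−5.90) and KRTAP2-3 (−4.05) fell. HYPK overlaps a neighbouring gene, so its value is uncertain, and KRTAP2-3 was not called with the term (adjusted p = 0.131).

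Interferon genes rose, 18 of 31 with none lower and a median of 0.73 (16 and 0.65 with library set as a term), including IFI44L (1.52), IFIT1 (1.17), IFIT3 (0.74) and SAMD9L (0.69). Tubule genes rose in 8 of 20 with none lower (7 higher and 1 lower with the term), including FXYD2 (1.66), the cadherin CDH16 (2.31) and GGT1 (0.54). Of 17 YAP and TAZ targets 5 fell, with CTGF at −1.86 and CYR61 at −0.99, and 11 fell with library set as a term. Of 30 proliferation genes 9 fell, such as CDK1 (−0.56) and CCNA2 (−0.53), and 16 fell with the term. The claudin CLDN1 (−2.77), the urokinase receptor PLAUR (−0.82), the protease ADAMTS1 (−1.25) and the cytokines TGFB2 (−1.08) and INHBA (−1.03) fell. In stress pathways the cystine carrier SLC7A11 (−0.92), MTHFD2 (−1.21) and STC2 (−1.34) fell, while DDIT4 rose by 0.66. Of 18 p53 targets 5 rose, with BTG2 at 0.93 and GDF15 at 0.89, and 2 fell, FAS among them (−0.54), but with the term 2 rose and 3 fell, and the median went from 0.28 to 0.08. The class I list had 7 of 15 genes higher, HLA-C at 0.48 among them, and TAP2 lower (−0.47), but with the term only 2 were higher and 1 lower, and the median went from 0.31 to 0.18. EPAS1, HIF1A, VHL, PAX8, VEGFA, VIM and CDH1 did not pass the test in any of the 3 CRISPRi groups.

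The test called 2357 of 15254 genes in iMAE-126, 947 higher and 1410 lower. On TPM with limma the split was 1177 higher and 698 lower, and the median of all genes differed by 0.13, with the cause not tested. With library set as a term 2551 genes were called, 1176 of them among the 2357, and 18 of 75 calls of named genes were lost. The camera test with the preset correlation called the NF-kB (adjusted p = 8.77e-09), interferon (2.23e-10), tubule (0.000505), proliferation (0.00172), class I (0.00302), YAP and TAZ (0.0432) and p53 lists (0.0266). The stress response (0.0432), immediate-early (0.0437) and heat shock lists (0.0437) were called downward. With an estimated correlation none was called, at 0.239 to 0.502. With library set as a term and an estimated correlation the YAP and TAZ list was called (0.00430). The others were not, at 0.118 for NF-kB and proliferation, 0.302 for interferon, 0.0819 for tubule, 0.507 for class I, 0.773 for p53 and the stress response, 0.636 for immediate-early and 0.324 for heat shock genes. Adjusted over the list alone, 19 NF-kB targets were lower, 24 interferon genes higher, 10 tubule genes higher and 2 lower. Without iMAE-126 replicate 1 the test called 151 genes and without replicate 2 it called 161, where the lone library is assumed to vary like the other groups. The absence of replicate 2 lost 64 of 75 calls of named genes. Those of MMP7, CFI, FXYD2, IFI44L, PLAUR, INHBA, SLC7A11 and CTGF held without either. The count was 3753 without SC replicate 1, 3853 without SC replicate 2 and 1554 without SC replicate 3.

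To ask whether iMAE-126 acts differently from the other guides, it was compared with the mean of iMAE-1.1 and iMAE-1.2. These guides share no library set, so without library set as a term the guide cannot be told apart from the set. With the term, the sets are linked by SC alone, with only SC replicates 1 and 2 in the set of iMAE-126. The term also assumes that the set shifts a gene equally in every group. With library set as a term F3 was lower in iMAE-126 by 2.46 (adjusted p = 2.24e-08), and CYP1B1 was higher by 1.77 (adjusted p = 3.08e-06). The log2 difference was −0.81 for C3orf14 and −0.77 for VPS9D1-AS1. It was 4.57 for MT1L, 0.72 for NNMT and 0.69 for MTSS1. These genes were chosen because iMAE-1.1 and iMAE-1.2 both changed them, which favours a difference. Interferon genes were higher in 22 of 31 (median 0.94), with 28 higher without the term (1.19), and their camera call (adjusted p = 1.83e-17) did not hold with an estimated correlation (0.0611). The tubule (0.0249), YAP and TAZ (0.00232) and sterol lists (0.0276) were called with both, 6 of 20 tubule genes higher, 10 of 17 YAP and TAZ targets lower and 7 of 21 sterol genes higher. On TPM the median of YAP and TAZ targets and of proliferation genes turned sign without the term. The test called 1811 genes with the term and 5760 without it, 996 of them in both. Without the term, 2852 genes were called without iMAE-126 replicate 1 and 2053 without replicate 2. On TPM with limma the split without the term was 4289 higher and 1471 lower against 2900 and 2860, and the median of all genes differed by 0.23, with the cause not tested. The log2 fold changes of iMAE-126 had a correlation across genes of −0.195 with those of iMAE-1.1 and −0.139 with those of iMAE-1.2, against 0.0944 and 0.0977 in the simulation. Controls of the same library set, SC replicates 1 and 2 for iMAE-126 and 3 to 6 for the others, gave −0.00337 and 0.0477. No control was shared there. With SC divided into groups of 3 libraries regardless of set, also without a shared control, the correlations averaged −0.267 and −0.217. They ranged from −0.561 to 0.0362 and from −0.525 to 0.0911, so they depended on which controls were used and not only on sharing.

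To ask whether genes that distinguish M1A move when the elements are repressed, genes that differed from 786-O by at least 1 on the log2 scale were tested as sets. In iMAE-126 the 532 genes higher in M1A moved in the direction of 786-O by a median log2 fold change of −0.30, with 129 genes lower and 12 higher. The 1036 genes lower in M1A moved up by a median of 0.49, with 254 higher and 11 lower. The camera test called these shifts (adjusted p = 2.47e-06 and 5.75e-16), and they held with an estimated correlation (1.70e-05 and 0.000599). They also held with library set as a term together with an estimated correlation (medians −0.26 and 0.49, adjusted p = 0.000120 and 0.00275). In iMAE-1.1 and iMAE-1.2 neither set was called, with adjusted p from 0.242 to 0.569 and medians from −0.08 to 0.00. The difference between iMAE-126 and the mean of the other guides, with library set as a term, was −0.33 for the higher set and 0.50 for the lower set. The adjusted p of camera was 1.73e-08 and 6.14e-15 with the preset correlation, and 0.000102 and 0.00413 with an estimated one. SC itself lay away from M1A in the same direction. Of 534 genes of the higher set 234 were lower and 44 higher in SC, and of 942 genes of the lower set 513 were higher and 19 lower. These sets share the M1A libraries with the comparison, which favours this direction. With sets from M1A replicate 1 and the change from M1A replicate 2, 135 of 496 genes of the higher set were lower and 10 higher, and 211 of 819 genes of the lower set were higher and 5 lower, with medians of −0.47 and 0.81. This removes the noise of single libraries, but not a deviation of culture or preparation that both M1A libraries may share.

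**Figure D3:**
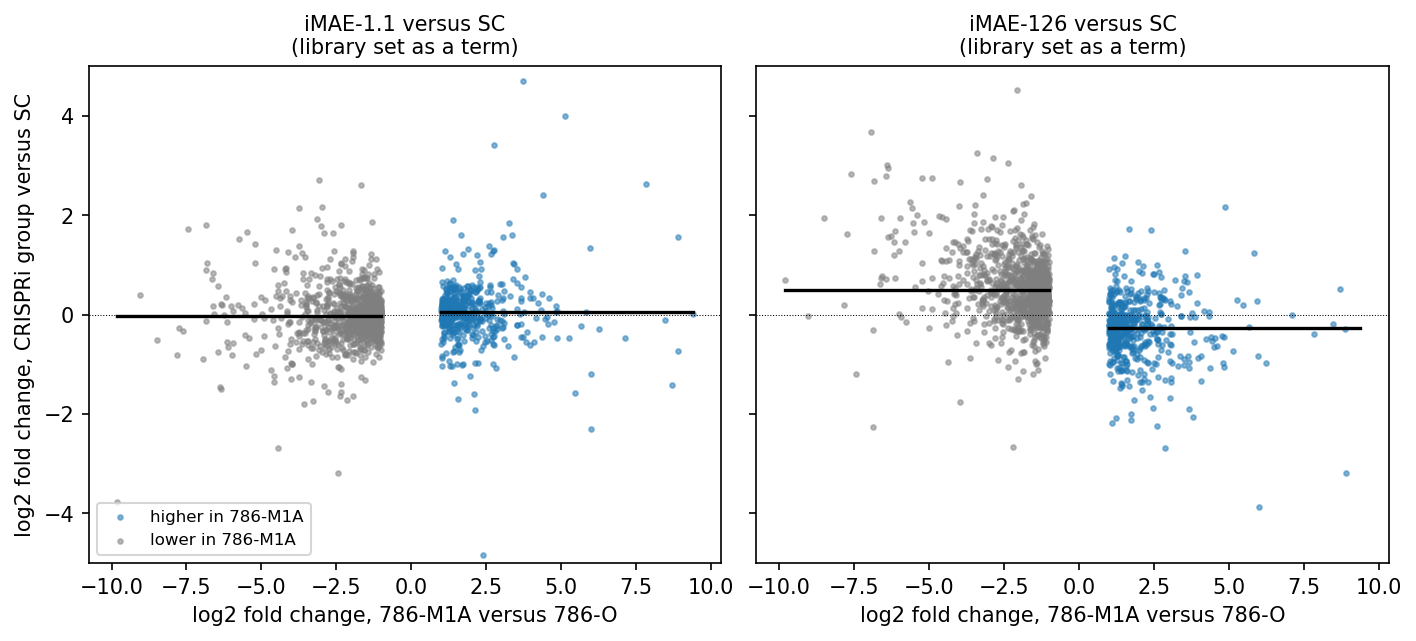
Log2 fold change of each gene in iMAE-1.1 and in iMAE-126 versus SC, with library set as a term, against its log2 fold change in M1A versus 786-O. Points are genes past the test with a change of at least 1 between the lines, and black lines mark the medians, −0.26 and 0.49 in iMAE-126.

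To compare a metastatic line of another origin, OS-LM1 was set beside M1A. Inflammatory genes were higher: 19 of 26 NF-kB targets rose, with the chemokines CCL20 (11.38), CXCL1 (7.65) and CXCL8 (4.79) and IL6 (5.78) among them, and 2 fell. The cytokines IL11 (5.97), CSF2 (4.24) and LIF (2.57) rose too. Genes with 0 counts in M1A included ADD2, a membrane skeleton protein (at least 2994-fold higher), TEKT4P2 (2533-fold), the glutamine synthetase GLUL (2110-fold), the guanine deaminase GDA (1997-fold), the WNT modulator SFRP2 (1578-fold) and C8orf4 (1364-fold). TEKT4P2 is a pseudogene, so its value is uncertain. PHGDH, the first enzyme of serine synthesis, was at least 737-fold higher. The hypoxia marker CA9 was 1126 times higher (95% counting interval 311 to 9312). DPYSL4 had 0 counts in OS-LM1 and was at least 706-fold lower, as were FAM45A (291-fold), MPDZ (240.4-fold), MDGA2 (239-fold) and SRGAP2B (234-fold), and the nucleotide carrier SLC17A9 was 7457 times lower (1338 to 294560). FAM45A and SRGAP2B have near-identical copies and are uncertain.

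Of 17 epithelial genes 10 rose and 2 fell in OS-LM1, and camera did not call the list (adjusted p = 0.0726). The rises included the junction genes DSP (8.16) and JUP (7.71) and CDH1 (3.04), while the collagens COL6A3 (−9.14) and COL4A1 (−7.62) fell. Genes of the tubule list rose in 12 of 21, such as FXYD2 (6.43) and PAX2 (3.60), and fell in 6, such as the renal lineage gene WT1 (−5.67). PAX8 rose by 1.41, HIF1A rose by 2.77 and VHL rose by 0.75. CYTIP fell by 7.43, and CXCR4 did not pass the test (0.71, adjusted p = 0.0658). Proliferation genes fell in 23 of 30, such as MCM4 (−1.65), sterol genes in 16 of 21, such as SQLE (−1.97), and heat shock genes in 10 of 12, such as HSPD1 (−1.77).

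The test called 11232 of 16354 genes, 5625 higher and 5607 lower in OS-LM1. The mean length of the genes that reads came from was 3617 and 3391 bases in OS-LM1 against 3929 and 3982 in M1A. The first OS-LM1 value lies in the range of set A of the CRISPRi libraries and the second in that of set B. The mean chi-square per gene between the OS-LM1 libraries was 30.2, against 7.43 in M1A and 5.51 in 786-O. A difference in library preparation cannot be told apart from the line. The camera test with the preset correlation called the NF-kB (adjusted p = 0.000374), proliferation (0.000916), sterol (0.0434) and heat shock lists (0.0434), and none with an estimated correlation (0.559 to 0.693). The tubule list was not called (0.211). Adjusted over the list alone, 19 NF-kB targets were higher and 23 proliferation genes lower. Over all 8 comparisons the preset correlation called 59 list results, and an estimated correlation without the library set ended each of those calls. In the fits of the lines and of SC with M1A, few residual degrees of freedom leave the estimated version little power. There its outcome does not decide whether a list call holds. Leaving out a library ended 8 of 123 calls of named genes, 7 of them without M1A replicate 1.

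**Figure D4:**
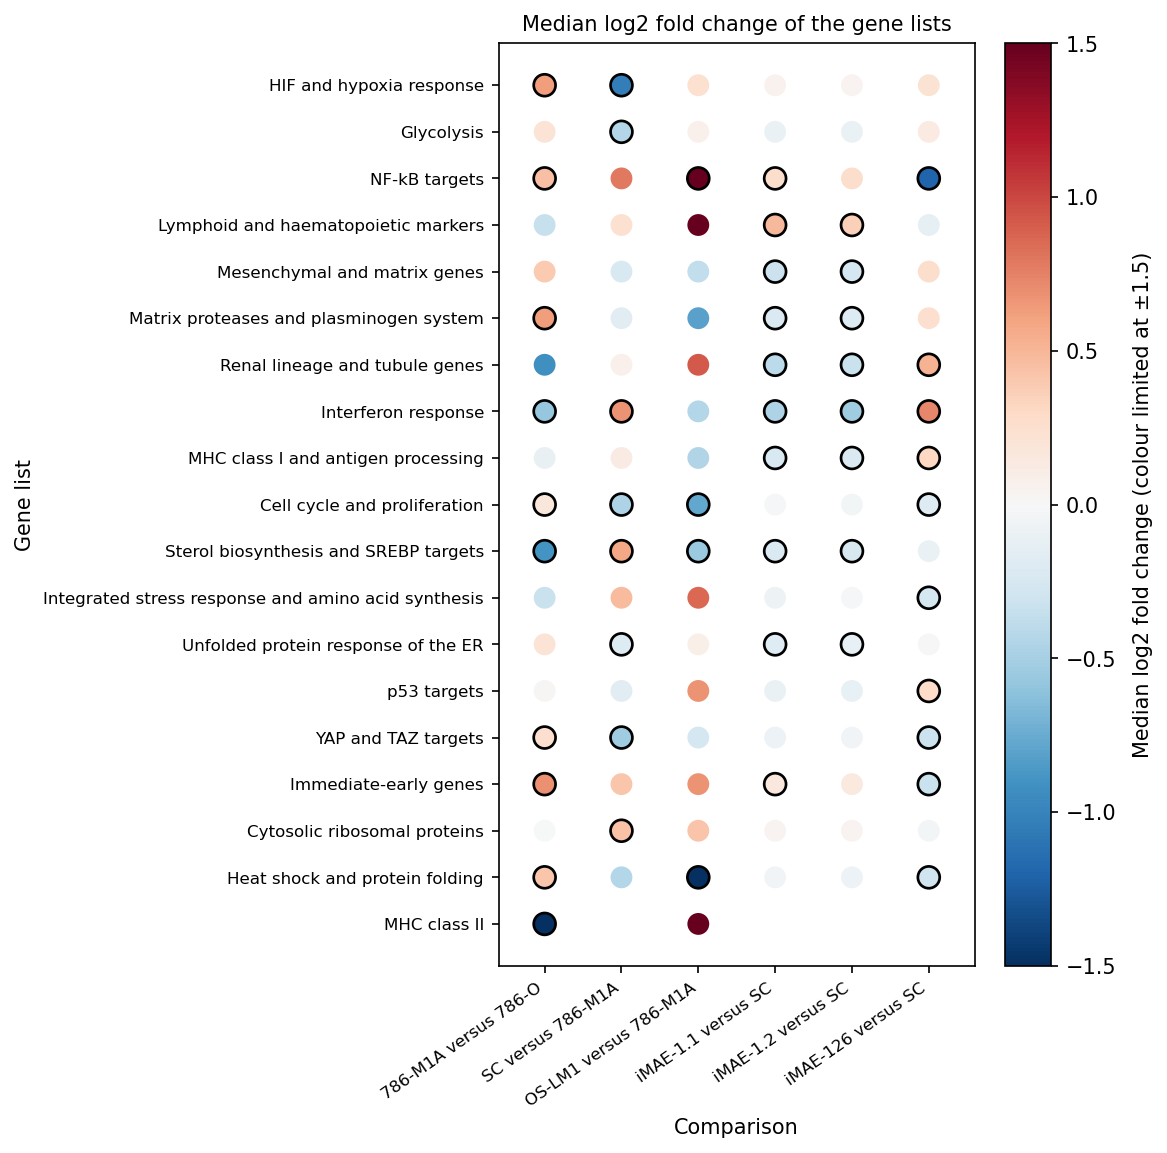
Median log2 fold change of the gene lists called by camera in at least 1 of 6 comparisons, as colour limited at ±1.5. Lists are on the vertical axis and comparisons on the horizontal axis, black rings mark adjusted p under 0.05 with the preset correlation, and the interferon list is −0.46 in iMAE-1.1 and 0.73 in iMAE-126.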

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

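All tests of explanations given here were chosen after the results were seen. Among 285 groups of libraries tested for single outlying values, 7 stood out, and chance marks about 1 in 20 groups. FXYD2 was at 2.87 CPM in SC replicate 5 against 1.52 to 1.95 in the other SC libraries, and GDF15 at 16.4 against 12.5 to 13.9 in the same library. LHX1 was at 35.5 CPM in SC replicate 6 against 29.0 to 31.4. In SC replicate 2, OAS1 was at 5.56 CPM against 7.72 to 8.67 and TRPM2 at 3.70 against 2.32 to 2.65. NNMT was at 109.8 CPM in iMAE-1.1 replicate 2 against 127.6 to 130.8, and ENO2 at 71.1 CPM in iMAE-1.2 replicate 3 against 79.1 to 79.8.

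Of 12 genes chosen because iMAE-1.1 and iMAE-1.2 both changed them, 9 differed between iMAE-126 and the mean of these guides with library set as a term (edgeR). The choice itself favours a difference, so these values do not measure how often the responses differ. PDGFRB (adjusted p = 0.0959), CCDC64 (0.105) and LUCAT1 (0.761) did not differ by the test. F3 differed by −2.46 (adjusted p = 2.24e-08), C3orf14 by −0.81 (0.00604) and VPS9D1-AS1 by −0.77 (0.0432). MT1L differed by 4.57 (1.52e-05), CYP1B1 by 1.77 (3.08e-06), NNMT by 0.72 (0.00110), MTSS1 by 0.69 (0.00360), TRIM6 by 0.63 (0.0177) and SYNM by 0.47 (0.0293). The genes higher in M1A differed by a median of −0.33 and those lower by 0.50. The adjusted p of camera was 1.73e-08 and 6.14e-15 with the preset correlation, and 0.000102 and 0.00413 with an estimated one.

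Genes of the metastatic line moved toward 786-O in iMAE-126. If 786-O cells had been mixed in, genes that M1A nearly lacks would reach 73.3% of their 786-O level, and their median was 0.170%. With library set as a term and an estimated correlation the genes lower in M1A still rose by 0.49 (camera adjusted p = 0.00275). The difference between the SC sets therefore does not account for the rise. Only SC lies in both sets, so the term cannot exclude that iMAE-126 was prepared apart from SC replicates 1 and 2. The mean length was 3528 and 3573 bases in iMAE-126 against 3646 and 3716 in SC replicates 1 and 2. After the trend with gene length was taken out (Spearman rho 0.0898 across genes, which are not independent replicates), the median was 0.48 against 0.49. The culture or clone history of the 2 libraries was not tested and may contribute to the 0.49.

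SC lay away from M1A in the same direction. A mixture with 786-O would need 77.1% at the same genes, and 0.0983% was found. The rise of the genes lower in M1A was 0.91 after the trend with gene length (rho −0.359 across genes) was taken out, against 0.94. It was 0.88 in SC replicates 1 and 2 and 0.91 in replicates 3 to 6, and since SC may have been prepared apart from M1A, batch remains open.

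The iMAE-1.1 and iMAE-1.2 libraries fell into 2 blocks that cross the guides: iMAE-1.1 replicates 1 and 2 with iMAE-1.2 replicates 3 and 4, and the others together. The split of the 8 libraries into these blocks called 1385 genes, against 0 for the labels and at most 0 in the others of 35 splits, so the structure lies in the libraries. Depth does not explain it, since the shallowest (9.06, in units of 1e6 counts) and deepest (23.7) libraries share a block, while the other spans 11.8 to 17.5. Nor does gene length (rho −0.0412 across genes, against −0.321 between the SC sets). Labels exchanged for 2 libraries of each guide, or a shared day of culture, could give the 1385 genes and cannot be told apart.

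When labels were exchanged between iMAE-1.1 and SC, 4 of 100 splits, the real labels among them, called at least the 69 genes of the real labels, the highest 952. For iMAE-1.2, 4 of 100 reached 110, the real labels again among them, and the highest was 2882. The exceeding splits hold SC replicates 1 and 2 in one group, but other splits that do so called 0 genes, so why these exceed was not settled. Within set B, against SC replicates 3 to 6, only the real labels of 35 splits reached 236 genes in iMAE-1.1 (next 0) and 383 in iMAE-1.2 (next 1). These splits treat the libraries as independent, although SC replicates 3 and 5, and 4 and 6, were closer to each other than the other pairs of these 4. Between iMAE-1.2 and iMAE-1.1 the real count was 0, which any of the 35 splits must reach, so this test decides nothing. The highest count was 1385.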

How the results depend on the processing

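Counts of called genes were moved by several choices, and the cause was not tested. DESeq2 called 424 genes in iMAE-1.1, 659 in iMAE-1.2 and 2 between these guides. With the compared groups alone 16 genes were called in iMAE-1.1, 17 in iMAE-1.2, 892 in iMAE-126 and 8733 in M1A versus 786-O. Without a filter iMAE-1.2 had 56. With a fold threshold the counts were 14, 22, 451 and 1308 for iMAE-1.1, iMAE-1.2, iMAE-126 and iMAE-126 versus the mean of the others, 1931 for M1A versus 786-O, 6128 for OS-LM1 and 2953 for SC versus M1A. SC replicates 1 to 4 gave 291 in iMAE-1.2 and 1207 in iMAE-126, and SC replicates 5 and 6 gave 5450 in iMAE-126.

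The replicate number as a block left 2 genes in iMAE-1.1, 2 in iMAE-1.2, 61 in iMAE-126 and 3086 in iMAE-126 versus the mean, and ended the CXCR4 call in iMAE-1.2 (−3.99, adjusted p = 0.0940) and iMAE-126 (−3.83, 0.0825). Numbers do not pair samples in general: same-number correlations were −0.763 to −0.286 between iMAE-1.1 and iMAE-1.2 and −0.524 between M1A and OS-LM1. The value was positive between M1A and 786-O, at 0.340. Between SC and iMAE-1.1 the values had both signs, −0.0814 to 0.302, and 2 of 4 passed 0.1. With the OS-LM1 numbers crossed the block called 11237 genes.

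Chosen after seeing the data, library set as a term gave 273 genes in iMAE-1.1, 417 in iMAE-1.2 and 1811 in iMAE-126 versus the mean, and SC replicates 3 to 6 gave 236 and 383. The term turned the camera direction of 3 list results. NF-kB targets in iMAE-1.1 went to −0.0396 (adjusted p = 0.739) and hypoxia genes in iMAE-126 versus the mean to −0.39 (0.000169). For the stress response in iMAE-1.2 the median was negative both without the term (−0.0202, 0.985) and with it (−0.0817, 0.0272). The adjusted p of these 3 lists are from camera with the preset correlation and may not hold with an estimated one. On TPM with limma CXCR4 passed in iMAE-1.1 (−0.80, 0.0234). Without a fold threshold on the set, genes lower in M1A passed in iMAE-1.1 (−0.0575, 0.0393).

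Leaving out a library gave 16 to 60 genes in iMAE-1.1 (lowest without iMAE-1.1 replicate 2), 11 to 103 in iMAE-1.2 (lowest without iMAE-1.2 replicate 4) and 151 to 3853 in iMAE-126 (lowest without iMAE-126 replicate 1). It gave 2053 to 5510 in iMAE-126 versus the mean (iMAE-126 replicate 2), 2259 to 2551 in M1A versus 786-O (786-O replicate 2) and 2002 to 9085 in SC versus M1A (M1A replicate 2). The fitted CXCR4 change ranged from −4.95 to −3.46 in iMAE-1.2 and −7.03 to −2.79 in iMAE-126. The −7.03 is fitted to iMAE-126 replicate 1 alone, at 0 CPM, so it is not a measured fold. The −4.95 rests on iMAE-1.2 replicate 1, at 0.107 CPM against 0 in replicates 3 and 4. An arm left with 1 library is assumed to vary like the others. Depth limits genes as low as CXCR4, since 3 counts equal 0.0569 to 0.331 CPM on library totals without TMM factors.

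Of 468 calls of named genes, 173 were lost without some library, 119 with the block, 64 with the compared groups alone, 39 with limma, 15 without the filter, 5 with RLE factors and 3 with DESeq2. Library set as a term ended 19 of 127. Of 59 list calls the estimated correlation ended 59, some of them in fits where few residual degrees of freedom leave it little power.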

Other observations

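F3, high in M1A (378 and 394 CPM) and low in 786-O (37.0 and 38.0 CPM), moved in opposite directions under the guides. In SC it lay at 127 and 136 CPM in set A and at 74.3 to 80.8 CPM in set B. In iMAE-1.1 and iMAE-1.2, which belong to set B, F3 was at 206 to 277 CPM. In iMAE-126, which belongs to set A, it was at 71.5 and 76.9 CPM, below both SC libraries of its set (log2 fold change −0.84 with library set as a term, edgeR adjusted p = 0.000494).

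CXCR4 was at 0 to 0.319 CPM in the 10 libraries with an iMAE guide, and its change passed the test in iMAE-1.2 and iMAE-126 but not in iMAE-1.1. The responses of iMAE-1.1 and iMAE-126 had a correlation across genes of −0.00337 with unshared controls, each of the library set of its guide. With unshared controls taken regardless of set it averaged −0.267, and genes are not independent replicates. The labels do not name the targeted elements, so whether CXCR4 lies near them was not tested.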
